A study of Caenorhabditis elegans with 11 samples.

How the data were processed

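Transcript levels were measured in whole adult hermaphrodites of Caenorhabditis elegans on 11 Affymetrix C. elegans Genome Arrays, 1 array per sample of total RNA. The arrays covered untreated worms (control, n = 4), worms exposed to oxygen (oxygen, n = 4) and worms with RNA interference (RNAi) against skn-1 and exposure to oxygen (skn-1 RNAi with oxygen, n = 3). Per the labels' protocols, biotin-labelled cRNA was made from 10 µg of total RNA. The labels and the design text give different strain numbers, so no strain is named here. The design text names 2 places of hybridisation and scanning without saying which array was processed where.

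The deposited values are intensities, 1 linear signal per probe set and array. They were computed with MAS5 in GCOS 1.4, per the submitters' processing notes. The notes state neither the scaling target nor the background settings, and detection calls are not used here. The mean signal without the lowest and highest 2% of probe sets was 250 to 251 on 7 arrays and 207 to 217 on the other 4, so the arrays had been scaled in 2 ways. The 4 arrays, control 1 and 2 and oxygen 1 and 2 (set 1), also held signal for the poly-A spike-in transcripts (median 105 to 211), which lay at 4.75 to 8.85 on the other 7 (set 2). These sets were found in the values and are stated in no label. Set 2 held 2 control, 2 oxygen and all 3 skn-1 RNAi arrays. Total signal per array was 6863700 to 9138000, and the number of arrays limits the precision. The labels do not state that samples came from separate cultures, so the p-values measure the spread between these samples.

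The table held 22625 probe sets, of which 77 were manufacturer's controls and were left out. GEO's platform annotation gave 20766 probe sets with 1 gene, 887 with several and 895 with none; genes are named only from the first kind. An update through gene identifiers, of which 20701 were found in the reference gene table (assembly WBcel235, used for names only), changed 0 symbols. A probe set was tested where at least 3 of the 11 arrays reached the 40th percentile of their own array, which left 15389 probe sets. The 1 signal of 0 was set to 0.1, the smallest positive value. Log2 signals were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on all 11 arrays with group as the term and no block. Tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets of a comparison and a threshold of 0.05. The 3 comparisons were oxygen against control, skn-1 RNAi with oxygen against oxygen, and skn-1 RNAi with oxygen against control. Log2 changes are given with their standard error, and group means of signal with their standard deviation (SD).

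Where every array of a group lay below its own 40th percentile for a probe set, the fold is a lower bound: the brighter group's geometric mean over that of the percentile, or of the probe set's own value where higher. The percentile stands in for a detection limit.

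Before the data were examined, 30 gene lists and 8 lists of tissue and cell type markers were fixed. The gene lists were glutathione S-transferases, UDP-glucuronosyltransferases, cytochrome P450, short-chain dehydrogenases, ABC transporters, SKN-1 targets from other work, antioxidant enzymes, cytosolic heat shock, ER unfolded protein response, mitochondrial unfolded protein response, HIF-1 targets, genes raised by DAF-16, genes lowered by DAF-16, proteasome, ubiquitin and proteolysis adaptors, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, oxidative phosphorylation, glycolysis and gluconeogenesis, NADPH supply, fatty acid metabolism, propionate shunt and B12, vitellogenins, collagens, C-type lectins, lysozymes and antimicrobial peptides, metal handling, RNA interference machinery, DNA replication and cell cycle, and DNA damage. The marker lists were for oocyte and germ line, sperm, intestine, body wall muscle, pharynx, neurons, epidermis, and embryo and larva. Some list names matched no tested gene and are not analysed here. Each of the 11657 genes was represented by its probe set with the highest mean log2 signal, and members are counted by it. Lists were tested with limma's camera (inter-gene correlation 0.01, at least 5 genes), which compares a list's changes with those of all other genes, adjusted over the lists of a comparison. A list whose median lies above 0 but below that of the other genes can therefore be called lower. Members were counted over all probe sets and adjusted over the list alone. With the correlation estimated from the data, 0 lists were called in each comparison, and that p is printed beside each call.

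The genes named follow a rule fixed at the same time. They are skn-1 and gst-4, whose GFP reporter in an indicator strain was checked in the study; per comparison the 10 largest increases and decreases among called genes whose groups did not overlap; per comparison and list up to 4 members with the smallest adjusted p; and the 10 with the largest opposite changes under oxygen and with RNAi. Others are said to have been chosen after their values were seen. In the 3 comparisons, 83, 22 and 73 named results were called in the order above, and 63, 12 and 31 of these kept the call without any 1 of the 11 arrays. Called genes of the rule that are printed without a leave-out value are of that kind.

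Replicate numbers recur in all 3 groups. For oxygen against control, the deviations of same-numbered arrays from their group means correlated at 0.565, 0.449, 0.489 and 0.523 across probe sets, so by the rule set for this work the numbers pair the samples. Differently numbered arrays of the same set correlated at 0.346 to 0.533 and arrays of different sets at −0.53 to −0.371, so these values mostly reflect the set.

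The comparisons share arrays. Correlations were therefore set beside 100 simulations of unchanged groups, and overlaps beside those of independent lists and beside splits of the shared arrays into 2 pairs with 1 array of each set. On simulated data with 200 of 15389 probe sets changed (5 runs), log2 changes of 2 were recovered in 55.7% of oxygen against control, 47.6% of skn-1 RNAi with oxygen against oxygen and 47.3% of skn-1 RNAi with oxygen against control; the shares for a log2 change of 4 were 87.3%, 86.4% and 83.8%. Of a log2 change of 1, 0%, 0.1% and 0% were recovered.

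Alternatives fixed beforehand were no filter, a filter at the 60th percentile, quantile normalization, median centring, a pseudocount of 9, eBayes with trend and robust, array weights, only the arrays of the 2 groups compared, the replicate number as a block, leaving out each array in turn, a 2-fold minimum, and, for lists, the estimated correlation, fry, and the mean over a gene's probe sets. Chosen after seeing the data were the set as a block, fits within each set, quantile normalization with the set block, the set block without control 4, and the set block with the estimated correlation.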

Results

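The series asked which transcript changes of C. elegans under high oxygen depend on SKN-1, a transcription factor of the Nrf family that controls detoxification genes. Worms grown at 25°C from the first larval stage, sterile and 3 days old, were kept untreated (n = 4 arrays) or held in 99% oxygen at 40 PSI and 20°C for 6 hours, without (n = 4) or with (n = 3) RNAi against skn-1. Signals of 22625 probe sets were given per array, with array medians of 27.4 to 79.1 and total signal of 6863700 to 9138000. The arrays fell into set 1 (control 1 and 2, oxygen 1 and 2) and set 2 (the other 7). With group in the fit 6828 of 15389 tested probe sets differed between the sets, 5669 of them higher in set 2. All skn-1 RNAi arrays were in set 2, so values with the set as a block stand beside the lists and counts they change. The set block ended 6 of 178 calls of named genes, all against control, and 7 of 44 list calls. Within set 2, with 7 arrays, 81 and 12 of these calls were not made. Control 4 stood farthest from its group, with a mean correlation of 0.822 to the other controls (0.888 to 0.893 for those). Worms with skn-1 RNAi but no oxygen, and worms on RNAi food without skn-1 RNAi, are not analysed here.

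The targeted gene, skn-1, had a mean signal of 535 ± 174 (SD, n = 4) in control, 510 ± 118 (n = 4) in oxygen and 347 ± 102 (n = 3) in skn-1 RNAi worms under oxygen. Its signals in the skn-1 RNAi arrays were 235, 371 and 435, against 417 to 681 in the oxygen arrays. The difference did not pass the test (log2 −0.58 ± 0.31, adjusted p = 0.547; −0.76 and 0.318 with the set as a block; −0.73 within set 2). The other 2 skn-1 probe sets changed by −0.35 ± 0.45 (adjusted p = 0.769) and 0.65 ± 0.81 (adjusted p = 0.759). With the set as a block they changed by −0.92 ± 0.22 (adjusted p = 0.11) and −0.48 ± 0.27 (adjusted p = 0.463). Within set 2 these changes were −0.82 and −0.41. Labels do not state which part of skn-1 the RNAi targeted, and probes inside that part can also measure the introduced RNA. The indicator gene gst-4, a glutathione S-transferase, rose 15.1-fold under oxygen, from 365 ± 283 to 4528 ± 522 (log2 3.92 ± 0.47, adjusted p = 0.00149). With skn-1 RNAi its signal was 1240 ± 516. Its log2 difference from oxygen of −1.94 ± 0.50 did not pass the test (adjusted p = 0.258, and 0.163 with the set as a block). Both skn-1 and gst-4 were fixed beforehand, whereas these p are adjusted over all 15389 probe sets. The unadjusted p of skn-1 in the limma fit was 0.0941. Not passing therefore does not show that either gene was unchanged by the RNAi.

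**Figure D1:**
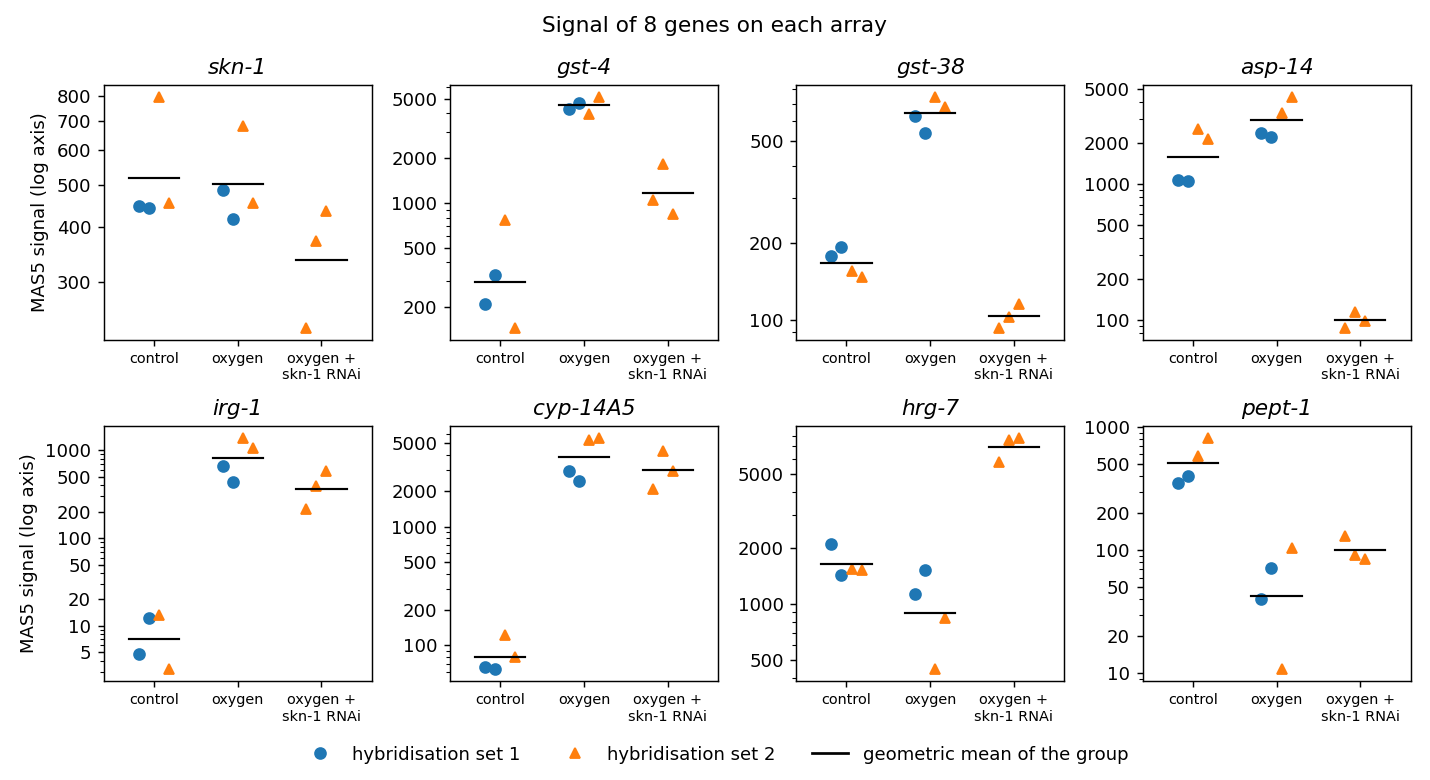
Signal of 8 genes on each of the 11 arrays, on a log axis in MAS5 signal units, by group. Circles are set 1, triangles set 2, and bars the geometric mean of the group; asp-14 lies at a mean of 99.5 in skn-1 RNAi worms under oxygen against 3068 in oxygen.

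Oxygen against control asked which transcripts respond to hyperbaric oxygen. For the exposed worms the labels give a pressure, a duration and a temperature below that of growth, and none of these for control. Pressure, the change of temperature and handling during the exposure therefore cannot be told apart from oxygen itself. Changes called raised or lowered by oxygen here are those of the whole exposure. Single genes such as irg-1, irg-2, parg-2, cyp-14A5 and mtl-1 rose, and pept-1 and nhx-2 fell. The infection response genes irg-2 and irg-1 rose at least 59.6-fold and at least 32.2-fold. The signal of irg-2 went from 7.30 ± 2.21 to 1936 ± 1412 (log2 7.74 ± 0.58, adjusted p = 0.00014). The gene of a poly(ADP-ribose) glycohydrolase, parg-2, rose 162-fold, from 18.7 ± 11.3 to 2514 ± 660 (log2 7.34 ± 0.56, adjusted p = 0.000143). The P-glycoprotein gene pgp-5 rose at least 29.6-fold, the transthyretin-like ttr-23 rose 57.3-fold, and C06B3.7, C06E4.3 and W06H8.2 rose at least 52.3-, 18.8- and 12.5-fold. The largest called decrease was in F46F2.3 (37.3-fold, log2 −5.22 ± 0.72, adjusted p = 0.00282).

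Of 17 tested SKN-1 targets from other work, 9 of which are also glutathione S-transferases, 12 rose and 0 fell (13 and 0 adjusted over the list alone), with a median log2 change of 2.32 (1.95 with dim genes at their bound). The list was called higher (adjusted p = 8.18e-17, and adjusted p = 0.0702 with an estimated correlation). Its members sdz-8 (18.2-fold), gst-30 (22.1-fold) and gcs-1 (3.18-fold), the rate-limiting enzyme of glutathione synthesis, rose from 73.1 ± 18.2 to 1323 ± 295, from 26.3 ± 14.9 to 542 ± 134, and from 471 ± 84.2 to 1526 ± 469, in that order. Of 35 glutathione S-transferases, 14 rose and 1 fell (20 and 5 adjusted over the list alone, median 1.46, or 0.81 with dim genes at their bound, adjusted p = 5.62e-08, and adjusted p = 0.0702 with an estimated correlation). Of 50 UDP-glucuronosyltransferases, which conjugate small molecules, 13 rose and 0 fell (24 and 1 adjusted over the list alone, median 1.16, adjusted p = 5.9e-12, and adjusted p = 0.0913 with an estimated correlation). Among them ugt-29 rose 48.6-fold and ugt-26 29.2-fold. Of 52 cytochrome P450 genes, 8 rose and 1 fell (14 and 3 adjusted over the list alone, adjusted p = 0.0311, and adjusted p = 0.608 with an estimated correlation). Of these cyp-14A5 rose from 83.0 to 4087 ± 1633 (log2 5.58 ± 0.37, adjusted p = 8.92e-05) and cyp-33C8 (42.5-fold). The P450 median of 0.21 was −0.06 after quantile normalization and after median centring, and the call ended with the set as a block (adjusted p = 0.0621) and without control 1 (0.0645), oxygen 1 (0.0542) or oxygen 3 (0.0504). Of 36 ABC transporters, 2 rose, pgp-5 and mrp-2 (5 and 1 fell adjusted over the list alone, median 0.52, adjusted p = 0.0271, and adjusted p = 0.613 with an estimated correlation). That call ended without control 2 (0.0674) or oxygen 4 (0.0942). Of 28 short-chain dehydrogenases, 3 rose (3 adjusted over the list alone, list adjusted p = 0.121), with dhs-14 at 4.83-fold.

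Among 29 antioxidant enzymes, 6 rose and 1 fell (7 and 1 adjusted over the list alone). The risers included the methionine sulfoxide reductase msra-1 (6.18-fold), gpx-7 (2.97-fold), the superoxide dismutase sod-4 (2.54-fold) and gcs-1. The list's median was 0.10 (adjusted p = 0.0304, and adjusted p = 0.27 with an estimated correlation), and −0.17 after median centring (adjusted p = 0.152). That call also ended with the set as a block (adjusted p = 0.0568) and without control 3 (0.235), oxygen 1 (0.0708) or oxygen 2 (0.241). Of 12 metal handling genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone, median 1.02, adjusted p = 3.55e-05, and adjusted p = 0.0702 with an estimated correlation). The metallothionein gene mtl-1 rose from 57.1 ± 26.6 to 1032 ± 629, the ferritin gene ftn-1 20.9-fold and cdr-4 15.2-fold. Of 14 genes raised by DAF-16, 3 rose (7 adjusted over the list alone, median 0.73, adjusted p = 0.0008, and adjusted p = 0.0984 with an estimated correlation). They were mtl-1, dod-3 (6.97-fold) and the catalase ctl-2 (2.73-fold, not called after median centring). Of 9 genes lowered by DAF-16, 2 rose (4 adjusted over the list alone, median 0.75, adjusted p = 0.015, and adjusted p = 0.111 with an estimated correlation). This call ended without control 3 (0.104), oxygen 1 (0.0529) or oxygen 2 (0.0792).

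Of 43 lysozymes and antimicrobial peptides, 8 rose and 0 fell (16 and 5 adjusted over the list alone, median 0.57; adjusted p = 0.0008, adjusted p = 0.257 with an estimated correlation and adjusted p = 0.105 within set 2). Besides irg-1 and irg-2, these included ilys-2 (log2 3.71) and cnc-4 (log2 3.67, and 3.03 without control 4). Of 97 C-type lectins, 4 rose and 2 fell (4 and 2 adjusted over the list alone, list adjusted p = 0.826), clec-47 by log2 3.59 and clec-67 by log2 2.77 upward. Of 15 ubiquitin and proteolysis adaptors, 4 rose and 0 fell (5 and 0 adjusted over the list alone, list adjusted p = 0.198, median −0.12, mean 0.63). These included the p62 homolog sqst-1 (7.47-fold) and, among ubiquitin ligase components, skr-5 (log2 3.72, and 3.09 without control 4; adjusted p = 0.0502 after quantile normalization) and skr-3 (4.29-fold). None of 33 proteasome genes was called singly. As a list they were called lower with a median of −0.17 (adjusted p = 0.000857, and adjusted p = 0.608 with an estimated correlation). It ended after quantile normalization (0.204) and without control 4 (0.0751).

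Of 15 intestinal markers, 1 rose and 3 fell (2 and 4 adjusted over the list alone, list adjusted p = 0.0782). The peptide transporter pept-1 fell from 537 ± 213 to 57 ± 40.7 (log2 −3.58 ± 0.62, and −2.92 without oxygen 3, adjusted p = 0.0102), the sodium/proton exchanger nhx-2 fell 3.95-fold, and the cathepsin B-like cpr-1 rose 2.35-fold. The peroxisomal acyl-CoA oxidase acox-1.2 fell at least 5.50-fold. Of 75 fatty acid metabolism genes 6 rose and 2 fell (9 and 2 adjusted over the list alone, list adjusted p = 0.838).

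Several large lists moved by small amounts with few or no single genes called. Lower were 54 mitochondrial ribosomal proteins (median −0.29, adjusted p = 2.69e-07, and adjusted p = 0.27 with an estimated correlation) and 24 oocyte and germ line markers with 1 called (1 adjusted over the list alone, −0.38, 3.95e-07, and adjusted p = 0.0984 with an estimated correlation). Also lower were 109 collagens with 2 called higher and 1 lower (2 and 0 adjusted over the list alone, −0.43, 1e-06, and adjusted p = 0.608 with an estimated correlation). So were 42 oxidative phosphorylation genes (−0.22, 6.75e-05, and adjusted p = 0.604 with an estimated correlation; 0.0669 after quantile normalization) and 25 DNA replication and cell cycle genes (−0.16, 0.00408, and adjusted p = 0.27 with an estimated correlation; 0.204 after quantile normalization). The median of 61 cytosolic ribosomal proteins was −0.18 (adjusted p = 3.05e-05, and adjusted p = 0.613 with an estimated correlation), 0.0079 after quantile normalization, and the call ended without control 4 (0.172). Neuron markers were higher (19 genes, 3 adjusted over the list alone, median 0.42, adjusted p = 0.0287, and adjusted p = 0.608 with an estimated correlation). Their call ended after quantile normalization (0.0671), after median centring (0.053) and without control 2 (0.0761), oxygen 3 (0.0553) or oxygen 4 (0.0991). No member was called among 19 cytosolic heat shock, 23 ER and 13 mitochondrial unfolded protein response genes (1 heat shock gene rose adjusted over the list alone, list adjusted p = 0.627, 0.29 and 0.52), 20 glycolysis genes (0.463), 5 vitellogenins (0.345) or 21 DNA damage genes (0.141). The same held for markers of sperm (39 genes, 0.127, and 0.00086 with the set as a block, or adjusted p = 0.579 with an estimated correlation), body wall muscle (16, 0.627), pharynx (16, 0.622), epidermis (12, 0.198) and embryo and larva (10, 0.282). In 10 HIF-1 targets and 11 NADPH supply genes 1 rose each (2 rose and 1 fell, and 1 rose, adjusted over the list alone, list adjusted p = 0.826 and 0.0819). The latter p was 0.047 with the set as a block, and adjusted p = 0.398 with an estimated correlation. In 16 propionate shunt and 21 RNA interference genes 1 fell each, also adjusted over the list alone (0.104 and 0.174). Without control 4, at the preset correlation, the RNA interference and DNA damage lists were called lower (adjusted p = 0.00743 and 0.00177) and the sperm markers higher (0.000495). Median, mean and test differed in sign for heat shock, ER unfolded protein response, ubiquitin adaptors, glycolysis, fatty acid metabolism and C-type lectins, none of them called.

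In all, 507 probe sets rose and 83 fell under oxygen, with median folds of 4.49 and 2.76. All 507 were higher and all 83 lower in each set (median log2 1.91 and 2.44, and −1.32 and −1.67, in sets 1 and 2). Both sets had entered these calls, and in 504 and 82 of them the groups did not overlap. The shared direction was therefore nearly fixed by the selection. With the set as a block 1137 rose and 288 fell (378 and 44 within set 2, 29 and 1 within set 1). The increases numbered 324, 307, 284 and 301 without control 1, control 2, oxygen 3 and oxygen 4. The decreases numbered 41, 43, 48, 46 and 53 without control 1, control 2, oxygen 1, oxygen 3 and oxygen 4. Median centring gave 162 decreases.

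The comparison of skn-1 RNAi with oxygen against oxygen asked which transcripts under oxygen depend on skn-1. With skn-1 RNAi, asp-14, dod-24, F55G11.2, gst-38 and gst-13 were lower, and gsto-1 and hrg-1 were higher. The aspartyl protease gene asp-14 fell 29.8-fold, from 3068 ± 1014 to 99.5 ± 13.1 (log2 −4.90 ± 0.38, adjusted p = 0.000963). The CUB-like domain genes dod-24 and F55G11.2 fell 50.6-fold and at least 15.2-fold, from 1286 ± 797 to 28.9 ± 19.3 and from 578 ± 108 to 18.2 ± 8.39. The log2 change of dod-24 was −5.66, and −4.85 without skn-1 RNAi array 3. Among glutathione S-transferases, gst-38 fell 6.23-fold to 104 ± 11.1 and gst-13 fell 6.96-fold to 285 ± 50.8, whereas the omega-class gsto-1 rose 15.2-fold, from 85.5 ± 44.5 to 1166 ± 269 (log2 3.93 ± 0.45, adjusted p = 0.00562).

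Further decreases were in C32H11.4 (log2 −4.46), F01D5.5 (at least 10.7-fold), F01D5.2 (at least 5.62-fold) and C14C6.5 (10.0-fold). The other increases were in the heme transporter gene hrg-1, from 418 ± 65.5 to 2464 ± 685 (log2 2.54 ± 0.29, adjusted p = 0.00556), in the sperm gene spe-18 (at least 3.43-fold), and in hrg-7 and hrg-4. The protease-like hrg-7 went from 985 ± 456 to 7039 ± 1080 (adjusted p = 0.0118; 0.0539, 0.0713 and 0.0659 without skn-1 RNAi array 1, 2 or 3). The heme transporter hrg-4 rose to 147 ± 20.3 (4.60-fold, adjusted p = 0.0175; 0.135 after quantile normalization), and its call ended without oxygen 1 (0.0589), 2 (0.0572) or 4 (0.0576) or skn-1 RNAi array 1 (0.103), 2 (0.0741) or 3 (0.0972). The decrease of sdz-8 (3.61-fold, adjusted p = 0.0339) had an adjusted p of 0.205 without skn-1 RNAi array 1 and was called only without control 1 or control 4 among the 11 leave-one-out fits.

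Over all probe sets, 28 were lower and 7 higher with skn-1 RNAi, at median folds of 6.90 and 5.80. With the set as a block 88 were lower and 28 higher, the 35 among them, and within set 2 10 and 8. Decreases numbered 43 without control 4, 14, 16 and 17 without oxygen 1, 2 and 3, and 13 without skn-1 RNAi array 1. Increases numbered 14 without control 4 and 3 each without skn-1 RNAi arrays 1 and 2.

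Of the 17 SKN-1 targets, 3 fell with skn-1 RNAi and 0 rose (8 and 0 adjusted over the list alone), gst-38, gst-13 and sdz-8. The list's median was −0.85, against 0.22 for all probe sets (adjusted p = 4.21e-14, and adjusted p = 0.0594 with an estimated correlation). With the set as a block these medians were −1.84 and 0.016. Of 35 glutathione S-transferases, 3 fell and 1 rose (10 and 1 adjusted over the list alone, median −0.56, adjusted p = 3.86e-10, and adjusted p = 0.0594 with an estimated correlation). None of 50 UDP-glucuronosyltransferases was called singly (5 fell and 1 rose adjusted over the list alone). Their list was lower (median −0.48, adjusted p = 2.98e-06, and adjusted p = 0.19 with an estimated correlation). Its median with the set as a block was −0.74. The 29 antioxidant enzymes were lower (4 adjusted over the list alone, −0.19, adjusted p = 9.65e-05, and adjusted p = 0.0594 with an estimated correlation; 0.0505 with the set as a block). So were 28 short-chain dehydrogenases (−0.23, adjusted p = 0.00135, and adjusted p = 0.151 with an estimated correlation; −0.15 and 0.0801 with the set as a block) and 12 metal handling genes (1 adjusted over the list alone, −0.50, adjusted p = 0.000714, and adjusted p = 0.0594 with an estimated correlation; 0.0601 with the set as a block).

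Lower too were 43 lysozymes and antimicrobial peptides (2 adjusted over the list alone, −0.39, adjusted p = 1.37e-05, and adjusted p = 0.125 with an estimated correlation). Within set 2 their adjusted p was 0.103. The 109 collagens were lower as well (−0.24, −0.01 with dim genes at their bound, adjusted p = 3.76e-07, and adjusted p = 0.64 with an estimated correlation). Their median with the set as a block was −0.62. Of 9 genes lowered by DAF-16, dod-24 fell (4 adjusted over the list alone, median −0.04, mean −1.21, adjusted p = 0.000859, and adjusted p = 0.0594 with an estimated correlation; −0.79 and 0.0973 with the set as a block). Higher were 19 cytosolic heat shock genes (1 adjusted over the list alone, 0.52, adjusted p = 0.00222, and adjusted p = 0.151 with an estimated correlation). So were 25 DNA replication and cell cycle genes (0.31, adjusted p = 0.0113, and adjusted p = 0.341 with an estimated correlation). That call ended after median centring (0.0899) and without oxygen 4 (0.115). Also higher were 16 body wall muscle markers (0.61, adjusted p = 0.000606, and adjusted p = 0.58 with an estimated correlation). With the set as a block the heat shock and muscle medians were 0.33 and 0.31. The 39 sperm markers had a median of 1.33 (adjusted p = 6.72e-06, and adjusted p = 0.723 with an estimated correlation) that was 0.18 with the set as a block (adjusted p = 0.0575). Among the lists not called, 1 C-type lectin of 97 fell (3 fell and 1 rose adjusted over the list alone, list adjusted p = 0.192). No member was called among cytochrome P450 (1 rose adjusted over the list alone, 0.192), ABC transporters (0.582), ER (0.0963) and mitochondrial (0.532) unfolded protein response, HIF-1 targets (1 rose and 1 fell adjusted over the list alone, 0.188), genes raised by DAF-16 (0.192), proteasome (0.452), ubiquitin adaptors (0.783), cytosolic (0.532) and mitochondrial (0.188) ribosomal proteins, oxidative phosphorylation (0.204), glycolysis (0.0933), NADPH supply (0.582), fatty acid metabolism (0.3), propionate shunt (0.0933), vitellogenins (0.0733), RNA interference (0.452) and DNA damage (0.506). The same held for markers of germ line (0.0933), intestine (1 rose adjusted over the list alone, 0.758), pharynx (0.452), neurons (0.0933), epidermis (0.452) and embryo and larva (0.572). With the set as a block the mitochondrial ribosomal, DNA damage and germ line lists were called higher (adjusted p = 0.00992, 0.0141 and 0.0159), and adjusted p = 0.443, 0.447 and 0.465 with an estimated correlation. Without control 4, at the preset correlation, 17 lists were called rather than 13. The ER unfolded protein response, then called higher, was among those gained (adjusted p = 0.0471).

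**Figure D2:**
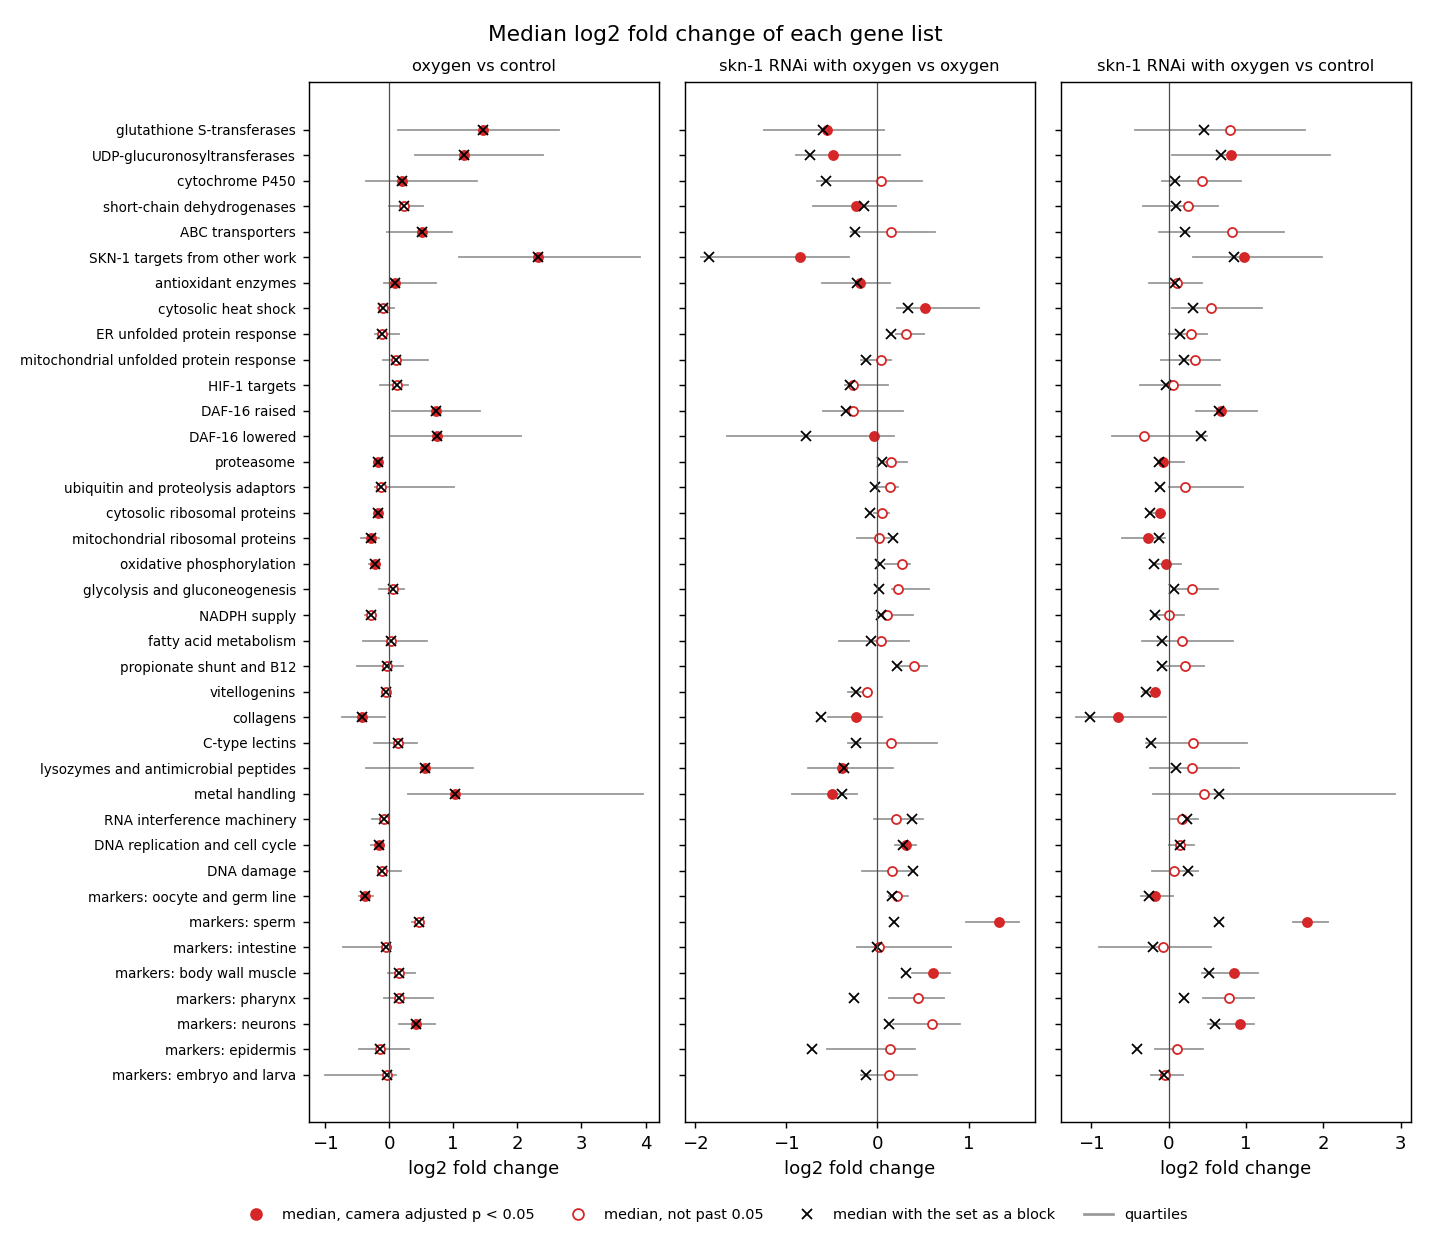
Median log2 change of each list in the 3 comparisons, with lines for the quartiles. Filled points are lists called by camera at the preset correlation and crosses give the median with the set as a block; the SKN-1 targets lie at 2.32, −0.85 and 0.97.

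The genes that oxygen raised and skn-1 RNAi lowered were counted as those responding to oxygen through skn-1 or alongside it. They numbered 16 probe sets, including gst-38, gst-13, sdz-8, F55G11.2, F01D5.5, C32H11.4, gst-32, srh-2, agns-1 and mbug-1. The decreases of gst-32, srh-2, agns-1 and mbug-1 with RNAi were not called in 7, 8, 9 and 4 of the 11 leave-one-out fits. Their highest adjusted p was 0.196, 0.196 and 0.143 for gst-32, srh-2 and mbug-1 (without skn-1 RNAi array 1) and 0.186 for agns-1 (without array 3). The oxygen increase of F01D5.5 was not called without control 2 (0.0508) or oxygen 4 (0.0504). The control, oxygen and skn-1 RNAi means were 168, 649 and 104 for gst-38, 407, 2012 and 285 for gst-13, and 161, 703 and 35.2 for C32H11.4. The reverse calls were made in 1 probe set, of spe-18. All 4 of its oxygen signals lay below the 40th percentile of their arrays and its control mean was 32.6, so no size is given for its decrease, which was not called without oxygen 1 (adjusted p = 0.0618) or oxygen 4 (0.0663). Of the 507 probe sets raised by oxygen, 415 (81.9%) lay below oxygen (median log2 −0.55).

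Independent lists would share 0.922 and 0.0378 probe sets. With the oxygen arrays split into 2 pairs with 1 array of each set, 1 to 3 probe sets were raised then lower (0.0434 to 0.124 for independent lists). Each comparison then held fewer oxygen arrays, and only 167 to 174 increases under oxygen and 4 to 11 decreases with RNAi were called. Part of the 16 may come from the shared oxygen arrays, but these splits cannot tell that from the loss of arrays. The set as a block gave 61 and 5 (13 to 20 raised then lower with the arrays split). The 16 became 27 without control 4, 9, 8, 9 and 9 without oxygen 1 to 4, and 7 without skn-1 RNAi array 1. Quantile normalization and median centring gave 33 and 31. Across probe sets, which are not independent replicates, the log2 changes of the 2 comparisons correlated at −0.280, against a simulated −0.296 (−0.325 to −0.270) with the set difference kept. Without a set difference the simulated value was −0.465, and with the set as a block the correlation was −0.349 against a simulated −0.422 (−0.450 to −0.392). The covariance was −0.157 (simulated −0.0936 to −0.0768 with the set difference kept, −0.169 on average without it), and with the set as a block −0.183 (simulated −0.0955 to −0.0776). With the oxygen arrays split into 2 pairs, so that none was shared, the correlation was −0.129 to −0.0609. Over all arrays it was −0.187 and −0.132 without control 3 and control 4. In unchanged groups the share below oxygen would be 71.0% (66.5 to 76.5%) with the set difference kept and 85.1% (80.9 to 88.6%) without it, and with the oxygen arrays split it was 81.0 to 85.2%. With the set as a block it was 87.2% of the 507 with the smallest p (simulated 76.5 to 85.6%). The simulated shares are of the 507 increases with the smallest p among unchanged probe sets, which noise alone picked. They therefore do not give the share that sharing would bring among called increases.

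**Figure D3:**
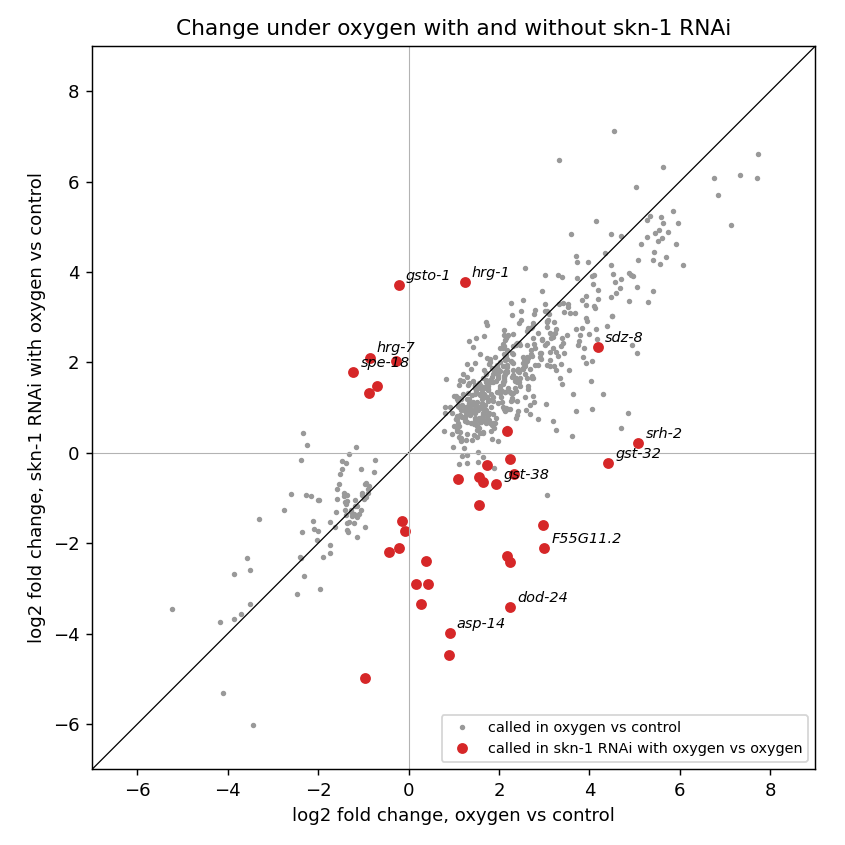
Log2 change of oxygen against control (x) and of skn-1 RNAi with oxygen against control (y), per probe set. Grey points are the 590 probe sets called under oxygen, red points the 35 called between skn-1 RNAi and no RNAi under oxygen, and the diagonal marks equal changes.

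The comparison of skn-1 RNAi with oxygen against control asked which changes were present when oxygen was given with skn-1 RNAi. Here too, pressure, the change of temperature and handling during the exposure cannot be told apart from oxygen. Single genes such as irg-1, irg-2, parg-2 and ugt-29 stood above control, and F01D5.2, asp-14 and pud-3 below it. Called increases included Y51B9A.8 (at least 10.6-fold, to 312 ± 195), irg-2 (at least 27.1-fold, to 753 ± 358), parg-2 (70.7-fold, to 1157 ± 580), irg-1 (at least 14.6-fold), C06B3.7 (at least 16.8-fold), ttr-23 (40.7-fold), pals-6 (at least 10.1-fold) and T16G1.5 (at least 3.89-fold). The secreted heme chaperone gene hrg-3 rose at least 14.1-fold, from 4.28 ± 3.03 to 380 ± 164 (adjusted p = 0.012; 0.0692 and 0.0554 without skn-1 RNAi array 2 or 3). Called decreases included pud-3 (64.8-fold, to 26.6, log2 −6.02 ± 0.74, adjusted p = 0.0027), asp-14 (15.9-fold), Y48E1B.8 (12.7-fold) and F01D5.2 (at least 3.02-fold).

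Of 50 UDP-glucuronosyltransferases, 8 rose and 0 fell (17 and 3 adjusted over the list alone, median 0.80, against 0.36 for all probe sets, adjusted p = 0.00995, and adjusted p = 0.716 with an estimated correlation). Here ugt-29 rose 26.8-fold and ugt-26 15.7-fold. Of 17 SKN-1 targets, 2 rose, gst-30 (17.7-fold) and sdz-8 (5.04-fold; 7 rose and 1 fell adjusted over the list alone). Their median was 0.97 (adjusted p = 0.0129, and adjusted p = 0.716 with an estimated correlation; 0.137 within set 2). Of 35 glutathione S-transferases, 5 rose and 2 fell (15 and 7 adjusted over the list alone, list adjusted p = 0.553), with gsto-1 at 13.1-fold. Of 52 cytochrome P450 genes, 6 rose (9 and 1 fell adjusted over the list alone, 0.331), cyp-14A5 by 37.3-fold. The signal of cyp-14A5 was 3113 ± 1114, near that in oxygen (4087 ± 1633). Of 36 ABC transporters, 4 rose (9 adjusted over the list alone, 0.179), pgp-5 at least 20.4-fold.

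The small heat shock gene hsp-16.41 rose 19.1-fold, to 284 ± 262 (log2 4.25 ± 0.61, and 3.54 without skn-1 RNAi array 3, adjusted p = 0.00645; 0.0534 after quantile normalization), and 2 of 19 cytosolic heat shock genes were called higher (5 adjusted over the list alone, list adjusted p = 0.107, and 0.0306 with the set as a block, or adjusted p = 0.616 with an estimated correlation). Of 97 C-type lectins, 5 rose and 7 fell (8 and 11 adjusted over the list alone, list adjusted p = 0.211, and 0.041, lower, with the set as a block, or adjusted p = 0.733 with an estimated correlation), clec-47 by 28.6-fold upward and clec-52 by 4.32-fold downward. Of 109 collagens, 7 fell and 1 rose (26 and 2 adjusted over the list alone). Their median was −0.65, or −0.34 with dim genes at their bound (adjusted p = 5.62e-17, and adjusted p = 0.716 with an estimated correlation). With the set as a block the collagen median was −1.02. An example, col-12, went from 3289 ± 835 to 1000 ± 367 (adjusted p = 0.0231; 0.0583 without control 1, and 0.0953 and 0.0772 without skn-1 RNAi array 1 or 2). Of 12 metal handling genes, 3 rose (5 and 1 fell adjusted over the list alone, 0.161, and 0.0293 with the set as a block, or adjusted p = 0.537 with an estimated correlation), with cdr-4 at 9.59-fold. Of 43 lysozymes and antimicrobial peptides 5 rose and 2 fell (8 and 3 adjusted over the list alone, 0.917).

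Markers of 39 sperm genes were higher (4 adjusted over the list alone, median 1.79, adjusted p = 4.33e-06, and adjusted p = 0.787 with an estimated correlation). So were those of body wall muscle (1 of 16, 8 adjusted over the list alone, 0.85, adjusted p = 0.00526, and adjusted p = 0.716 with an estimated correlation). Neuron markers were higher too (2 of 19, 6 adjusted over the list alone, 0.93, adjusted p = 0.0031, and adjusted p = 0.716 with an estimated correlation). With the set as a block the sperm, muscle and neuron medians were 0.65, 0.52 and 0.60. Genes raised by DAF-16 were higher (3 of 14, 3 adjusted over the list alone, 0.68, adjusted p = 0.0271, and adjusted p = 0.716 with an estimated correlation). Here the call ended after median centring (0.0644) and without control 4 (0.132) or skn-1 RNAi array 2 (0.0676). Lower were 54 mitochondrial ribosomal proteins (−0.27, adjusted p = 8.85e-09, and adjusted p = 0.716 with an estimated correlation). Their median with the set as a block was −0.13. Also lower were 24 germ line markers (−0.18, adjusted p = 0.0031, and adjusted p = 0.716 with an estimated correlation). The germ line adjusted p was 0.326 after quantile normalization.

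The median of 61 cytosolic ribosomal proteins was −0.11 (adjusted p = 2.24e-05, and adjusted p = 0.787 with an estimated correlation) and 0.0154 after quantile normalization. Called lower relative to all genes were also 33 proteasome genes (median −0.07, mean 0.00079, adjusted p = 0.0333, and adjusted p = 0.787 with an estimated correlation), 42 oxidative phosphorylation genes (median −0.03, mean 0.02, adjusted p = 0.0257, and adjusted p = 0.787 with an estimated correlation) and 5 vitellogenins (1 adjusted over the list alone, −0.18, adjusted p = 0.0257, and adjusted p = 0.716 with an estimated correlation). After quantile normalization their adjusted p were 0.747, 0.879 and 0.419. With the set as a block the medians of these 4 lists were −0.24, −0.12, −0.19 and −0.30. These 4 calls ended without control 4 (0.2, 0.531, 0.531 and 0.2), and the last 3 also without skn-1 RNAi array 1 (0.132, 0.0599 and 0.0669). Not called were short-chain dehydrogenases (1 rose and 1 fell of 28, also adjusted over the list alone, 0.478), antioxidant enzymes (2 of 29 rose, 3 adjusted over the list alone, 0.504), HIF-1 targets (1 of 10 fell, 1 rose and 1 fell adjusted over the list alone, 0.504), genes lowered by DAF-16 (1 rose and 1 fell of 9, 2 and 2 adjusted over the list alone, 0.382), ubiquitin adaptors (2 of 15 rose, 5 adjusted over the list alone, 0.227), fatty acid metabolism (2 rose and 2 fell of 75, 7 and 3 adjusted over the list alone, 0.377) and propionate shunt (1 of 16 rose, 1 adjusted over the list alone, 0.735). Intestine (1 of 15 fell, 1 rose and 3 fell adjusted over the list alone, 0.112) and epidermis markers (1 of 12 fell, 1 adjusted over the list alone, 0.107, and 0.0293 with the set as a block, or adjusted p = 0.365 with an estimated correlation) were not called either. No member was called by its representative probe set in ER (0.701) and mitochondrial (0.917) unfolded protein response, glycolysis (0.59), NADPH supply (1 rose adjusted over the list alone, 0.348), RNA interference (0.61), cell cycle (0.701), DNA damage (0.504), pharynx (0.348) and embryo and larva (1 fell adjusted over the list alone, 0.211).

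Against control, 383 probe sets were higher and 131 lower, at median folds of 4.63 and 3.08. With oxygen against control 236 and 44 of these were shared. Independent lists would share 12.62 and 0.707, and the control arrays split into 2 pairs gave 57 to 85 and 3 to 8 (1.62 to 2.28 higher in both for independent lists). Quantile normalization gave 208 higher and 220 lower, median centring 218 and 322, and the set as a block 457 and 242 (228 and 58 within set 2). Without control 1 and control 2 the increases numbered 193 and 196 and the decreases 67 and 68. Without 1 of the skn-1 RNAi arrays the increases numbered 87 (array 2) to 146 (array 1) and the decreases 32 to 51.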

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

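The tests by splits that keep the pairs or sets apart, of set differences, of a lost oxygen response, of shared oxygen arrays and of food were chosen only after their results were seen.

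The 28 probe sets lower with skn-1 RNAi under oxygen, such as asp-14, dod-24 and gst-38, are the first pattern. Within set 2 their median log2 change was −2.92 against −2.79 over all arrays. The 28 were chosen on these same arrays, with every skn-1 RNAi array below every oxygen array. A decrease within set 2 was thus fixed by the selection, and it does not test a difference between the hybridisation sets as the cause. Among them, 14 were called below control, including asp-14 and F01D5.2. Of these, 12 were not called raised by oxygen, so they had no called increase to lose. Being lower with RNAi but not called above control under oxygen nearly fixes a call below control. These 12 therefore do not test a lost oxygen response. The other 2, F01D5.5 and C32H11.4, were called both raised by oxygen and below control. A loss of the oxygen increase alone would not take them below control. The calls below control of F01D5.5 and C32H11.4 ended in 4 and 2 of the 11 leave-one-out fits, so this evidence is weak. Those of dod-24 and pud-4 ended in 3 and 1 fits, and those of asp-14, F01D5.2 and clec-52 in 0. The remaining members of the 14 were not named by the rule against control, and their calls were not followed through these fits. For the 14 not called below control, such as gst-38 and gst-13, a lost oxygen response was not tested either. Being lower with RNAi but not below control nearly fixes that they stood above control under oxygen. A dependence on skn-1 without oxygen stays open for both parts, since no such arrays are analysed here. The bacterial food or culture of the skn-1 RNAi worms also cannot be told apart from the RNAi for any of the 28. No arrays of worms on RNAi food without skn-1 RNAi are analysed here.

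The second pattern is the 16 probe sets raised by oxygen and lower with skn-1 RNAi, for which shared oxygen arrays could give such an overlap. With the oxygen arrays split into 2 pairs, so that the comparisons shared none, and the set as a block, at least 13 and at most 20 probe sets were raised then lower, against 0.855 to 1.74 for independent lists and 0 to 2 raised in both. That excludes the sharing as the whole cause of such genes with the set as a block. Without the block the splits gave 1 to 3 (0.0434 to 0.124 for independent lists). Fewer oxygen arrays per comparison also lower this count, so it cannot tell how many of the 16 come from the shared arrays. Part of the 16 may still come from them.

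The third pattern is that hrg-1, hrg-4 and hrg-7 were higher with skn-1 RNAi under oxygen. Their median log2 change within set 2 was 2.63. These genes were chosen on the same arrays, with groups that did not overlap, so this value does not test a difference between the sets as the cause. The bacterial food or culture of the skn-1 RNAi worms may account for the pattern and cannot be told apart from the RNAi, since 0 arrays came from worms on RNAi food without skn-1 RNAi. A biological dependence of heme genes on skn-1 stays open, as untested.

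In other splits of the samples, the numbers were taken to pair the control and oxygen arrays by the rule set for this work, which no label states. Only 8 splits part every such pair, too few for a share under 5%. Of these, 1 of 8 was as large as the real split (590, highest other 0), and with the set as a block also 1 of 8 (1425, highest other 0). Among all 35 splits, which otherwise keep some pairs together, the split that follows the sets gave 5939, which points to a structure of the arrays; within set 2, 378 rose and 44 fell. For both comparisons of skn-1 RNAi with oxygen, 10 splits keep the number of arrays of each set per group, too few for a share under 5%. Against oxygen 1 of 10 was as large as the real split without the block (35, highest other 0) and 1 of 10 with it (116, highest other 0). Against control the real counts were 514 and, with the block, 699, each reached by 1 of 10 (highest other 1 in both).

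Of 110 groups of 4 arrays tested, 7 held an array far from the others by Dixon's criterion, where chance gives about 1 in 20 groups. Control 3 stood high in F55G11.2 (236.2, others 42.4 to 51.9), in gst-13 (613, others 328 to 353) and in skn-1 (797, others 442 to 454). Control 1 stood high in gsto-1 (135, others 75.6 to 76.0), and oxygen 1 low in F01D5.2 (148, others 229.9 to 242). Control 4 had a lower ratio of 3' to 5' signal for the gapdh control (0.918, others 1.14 to 1.17) and a lower mean correlation with its group (0.822, others 0.888 to 0.893).

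Among 15 manufacturer's control probe sets for worm genes, outside the main measurement, the 3 of catalase rose under oxygen, by log2 1.44, 1.13 and 1.31 (adjusted p = 0.00598, 0.0164 and 0.00598). With skn-1 RNAi and oxygen they stood above control by 1.31, 1.67 and 1.56.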

How the results depend on the processing

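The set block, with or without control 4, and fits within a set were chosen after seeing the data. Counts are given in the order oxygen against control, skn-1 RNAi with oxygen against oxygen, then skn-1 RNAi with oxygen against control, higher before lower; the causes of the changes were not tested except where fewer arrays or probe sets entered a fit. The direction of each called named gene was the same under every alternative. Of 178 such results 116 kept the call under all alternatives fixed beforehand other than the leave-one-out fits. Under all leave-one-out fits 106 kept it, and under all alternatives added later 57. Of 44 list calls 31 held in all leave-one-out fits, and 0 under the estimated correlation. The 2-fold minimum and the mean over probe sets moved no count by over 1.5 times. Without detection calls, signal over background limits the dim probe sets.

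Without the filter, 39 probe sets fell under oxygen, 4 rose and 16 fell with skn-1 RNAi against oxygen, and 195 rose and 67 fell against control, with 8 raised then lower and 0 in reverse. The 60th percentile filter gave 139 lower, 22 and 43, and 230 lower, with 27 raised then lower and 2 in reverse. Quantile normalization gave 50 lower against oxygen, 208 and 220 against control, and 33 and 2 opposite. Median centring gave 162 lower, 50 lower, 218 and 322, and 31 and 3 opposite. The pseudocount gave 19 and 44 against oxygen and 30 raised then lower. Trend and robust gave 16 and 44, 204 lower against control, and 28 and 2 opposite. Array weights gave 1039 and 165, 293 and 175, 7493 and 1999, and 78 and 13 opposite. The correlation was then −0.00505, and 5 lists were called against control. The weights of control 1 to 4 were 2.25, 5.55, 0.319 and 0.144, so the control mean rested mostly on set 1. All skn-1 RNAi arrays were in set 2, so the weighted counts against control cannot be told apart from the set difference. With only the 2 groups compared, 306 rose and 40 fell under oxygen, and 16 fell with skn-1 RNAi against oxygen. The estimated correlation gave 0, 0 and 0 lists and fry 10, 6 and 6, against 18, 13 and 13.

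The replicate block gave 565 and 94 under oxygen, 19 higher against oxygen, 1364 and 305 against control, and 7 lists against control. Numbers 1 and 2 lie in set 1 for control and oxygen but in set 2 for skn-1 RNAi. The block thus treats the set difference as one of numbers and applies it to skn-1 RNAi arrays 1 and 2. Its counts with skn-1 RNAi therefore cannot be told apart from the set difference. The skn-1 RNAi arrays share only a number with the others (correlations of deviations −0.00446, −0.0988 and −0.128 with oxygen, −0.0338, −0.12 and −0.107 with control), and not every one correlated best with its own number. For oxygen against control, the block changed no count by over 1.5 times.

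The set block gave 1137 and 288, 28 and 88, 242 lower against control, and 61 and 5 opposite. Set 1 alone gave 29 and 1 under oxygen. Set 2 alone gave 44 lower under oxygen, 10 lower against oxygen, 228 and 58 against control, 7 and 2 opposite, and a correlation of −0.458. Quantile normalization with the set block gave 323 lower, 40 and 76, 286 lower, and 45 and 8 opposite. The set block without control 4 gave 1065 and 224, 53 and 146, 102 and 10 opposite, and a correlation of −0.386. The set block with the estimated correlation gave 0, 0 and 0 lists.

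Leaving out 1 array at a time gave 284 to 522 and 41 to 73 under oxygen, 3 to 14 and 13 to 43 against oxygen, 87 to 494 and 32 to 146 against control, 7 to 27 raised then lower, 0 to 2 in reverse, a correlation of −0.387 to −0.132, and a log2 change of skn-1 of −0.762 to −0.319. The lists called numbered 16 to 19, 13 to 17 and 8 to 14, the 8 without control 4.

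The median of the cytosolic ribosomal proteins reversed after quantile normalization (0.0079 under oxygen and 0.0154 with skn-1 RNAi against control; 0.0079 and 0.0235 with the set block too). The uncalled mitochondrial ribosomal list of skn-1 RNAi against oxygen was tested as lower and turned to higher with the set block (0.171), within set 2 (0.208) and with the set block without control 4 (0.175).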

Other observations

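The genes and tests of this part were chosen after their values were seen. Of them, hrg-1, hrg-4 and hrg-7 had been named by the rule against oxygen, and only their values against control were chosen here. Heme genes beyond those named by rule were followed over the 3 groups. The heme exporter gene mrp-5 had means of 673 ± 122, 880 ± 172 and 1267 ± 37.3 in control, oxygen and skn-1 RNAi worms under oxygen, and the last differed from control by log2 0.93 (adjusted p = 0.0579, not called). Its other probe set was called higher than control (log2 2.25, adjusted p = 0.0391). The gene hrg-9 rose under oxygen from 12.7 ± 6.23 to 93.0 ± 28.4 (adjusted p = 0.00282) and stood at 57.4 with skn-1 RNAi. Against control, hrg-1 was higher with skn-1 RNAi by log2 3.78 (adjusted p = 0.00076) and hrg-7 4.29-fold (adjusted p = 0.0163). There hrg-4 was higher by log2 1.33 (adjusted p = 0.0441, and 0.0579 with the set as a block). In oxygen against control, hrg-1 rose by log2 1.24 (adjusted p = 0.029). The changes of hrg-4 and hrg-7 under oxygen were −0.87 and −0.86 (adjusted p = 0.144 and 0.273, not called).

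Among the 28 probe sets lower with skn-1 RNAi under oxygen were those of cbl-1, pdxk-1, nhr-61, F01D5.1 and F01D5.3. The gene cbl-1, a cystathionine lyase homolog, rose under oxygen and was lower with skn-1 RNAi in each of its 2 probe sets (log2 1.64 and 1.55 under oxygen, −2.28 and −2.08 with RNAi). The pyridoxal kinase gene pdxk-1 rose by 1.09 (adjusted p = 0.025) and was lower with RNAi by −1.67 (adjusted p = 0.025). The nuclear hormone receptor gene nhr-61 rose by 2.17 and was lower by −1.69. F01D5.1 was lower by −2.72.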
